A study of Mus musculus with 4 samples.

How the data were processed

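The series holds strand-specific RNA sequencing of 4 mouse T cell samples in 2 experiments. Total RNA was purified with a PureLink RNA Mini kit and libraries were made with a SureSelect strand-specific kit, per the labels' protocols. The submitters' processing notes name Cufflinks and the mouse build mm9, with no versions. The aligner, the gene annotation and the use of strand in the quantification are not given in the sources used here. Each library was placed in its group by its title, and each table column was matched to a library by its name and that title.

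The deposited DSS table holds linear FPKM per gene for untreated and DSS Treg and a fold change, which the authors computed as the ratio of DSS to untreated. Recomputing that ratio from the 2 FPKM columns gave the deposited value within a relative difference of 0.000448. FPKM divides the fragments of a gene by its length and by the number of fragments of the library, so it does not keep the counts. The deposited vector table holds log2(FPKM + 1) values and a log2 fold change that the authors computed as their difference, to within 5e-10. That scale was read from the values themselves, since 2 to the power of the value, less 1, gave numbers of 6 significant digits. These were turned back to FPKM before use. The DSS table lists genes with an FPKM above 1 in at least 1 library (the lowest such value is 1.00036), so a gene below that level in both libraries is not seen. The 2 tables were made separately, and changes were taken only within a table.

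Rows whose gene name had been turned into a date by a spreadsheet were left out, 16 in the DSS table and 25 in the vector table, holding 0.261% to 0.263% and 0.200% to 0.218% of the summed FPKM. No symbol occurs more than once in either table. Gene symbols are given as in the tables. The reference used here is the GENCODE vM21 annotation on GRCm38, another build than the authors', so no coordinates are given and it served only for transcript lengths and current names.

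The change of a gene is the difference of log2(FPKM + 1) between the libraries of an experiment, treated minus untreated or Sox12 minus mock vector. This understates the change of low genes, and a ratio in the text is of the FPKM themselves. Genes with a mean of both libraries of at least 1 FPKM passed the filter. With 1 library per group no test was run and no p-value is given. A gene counts as at least 2 times higher or lower when its change is at least 1 in size on the log2(FPKM + 1) scale.

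Named genes followed a rule written before the data were examined. It takes Sox12 and Foxp3 in every library, and per experiment the 10 genes with the largest change in each direction among those with a mean of at least 5 FPKM, leaving out predicted genes, most small RNAs and receptor gene segments. Of each of 34 gene lists fixed beforehand it takes up to 4 members with a change of at least 1, or else the 2 with the highest mean. Genes past the size rule in both experiments were also named. A few genes that the rule takes are not used here. The median change of a list with at least 3 members past the filter was placed among 10000 random lists of the same size, drawn from 20 classes of mean expression, as a percentile that describes these libraries. In the neutrophil and platelet lists of the vector experiment and the dendritic cell list of the DSS experiment 0 members passed the filter.

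Depth in the vector table was taken from its low values, which are multiples of what 1 fragment is worth. The ratio of the libraries came from genes with both values below 0.1 FPKM. The number of fragments was sought among 4559 genes with a single transcript in the reference, as the most frequent value of 1 divided by FPKM and length. In the mock and Sox12 vector libraries 384 and 433 genes lay between the limits searched, and 24 and 23 at the most frequent value. The number of fragments thus rests on few genes. It is not corrected for fragment size and so errs on the low side. Counting error covers neither the preparation of the library nor the animals.

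The counting and list steps were tested on simulated data for the comparison of the Sox12 and mock vectors, with Poisson fragments at the mock vector depth and 200 changed genes. Of 67 genes changed 1.5-fold, 0 passed the size rule, as it intends. Of 67 genes changed 2.5-fold, 58 passed, and of 66 genes changed 4-fold, 62 passed. Of 10401 unchanged genes 0 passed. Both simulated libraries were drawn from the mock vector values with counting error alone, every transcript taken as 2 kb. The simulation therefore does not show how many genes differences between preparations or animals would carry past the rule. A list of 19 genes shifted by 0.3 lay at percentile 100, and 11 of 200 unchanged lists of 15 genes lay outside the central 95%. The unchanged lists were random draws of the genes they were ranked against, so their share outside was set by construction.

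Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter or a filter at a mean of 5 FPKM, the median change set to 0, equal 75th percentiles, equal totals without the 20 highest genes, the highest row per symbol, a size rule of 1.5 and, for lists, members of 1 list only. Counts without small RNAs and unnamed loci were added after the data had been seen. Percentiles under alternatives used 2000 random lists. A count was called moved when it differed by more than 1.5 times. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.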

Results

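RNA was sequenced from mouse T cells in 2 separate experiments, each with 1 library per group and 4 libraries in all. The first compared splenic regulatory T cells (Treg), sorted from Balb/c mice that carry a human CD2 reporter at Foxp3, between an untreated group and a group that drank water with 3% dextran sulfate sodium (DSS) for 7 days. DSS is a polymer that injures the colon epithelium and causes colitis in mice. The second compared naive CD4 T cells of wild-type C57BL6 mice after transduction with a mock vector or with a vector carrying Sox12, a transcription factor of the SoxC group. The series title names the question, which is how Sox12 relates to the induction of Treg. With 1 library per group no difference below has a replicate check, so both values are given and genes are named by a rule of size.

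The DSS table listed 10679 rows, each with an FPKM above 1 in at least 1 library, and 10545 genes passed the filter of a mean of at least 1 FPKM. The vector table listed 23284 rows, of which 10822 genes passed it. Its low values allowed the depth to be recovered. Among 1541 genes with both values below 0.1 FPKM, the most frequent ratio of Sox12 vector to mock vector was 0.957 (290 genes), so the Sox12 vector library held about 1.05 times as many fragments. With transcript lengths of a later annotation, 1 FPKM rested on about 42.6 fragments per kb of transcript in the mock vector library and 45.3 in the Sox12 vector library. In a transcript of 2 kb this came to about 85.3 and 90.5 fragments, which gives a counting error of 10.8% and 10.5%. The absolute depth of the DSS libraries is unknown, because only genes above 1 FPKM were listed.

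Sox12 was present at a low level in the Treg libraries and was higher in the DSS library. It had 0.715 FPKM in untreated Treg and 1.52 FPKM in DSS Treg, a log2 change of 0.55 on the log2(FPKM + 1) scale. The fold change in the authors' deposited table was 2.12, which ranked 54 among the named genes of that table, counted from the highest. On the log2(FPKM + 1) scale its change ranked 111 among the genes past the filter. Only its value in the DSS library exceeded 1 FPKM, the level for listing. Markers of erythroid and myeloid precursors were also higher in the DSS library. The values do not show which cells the Sox12 transcripts came from. In the vector experiment Sox12 had 1.56 FPKM with the mock vector and 829 FPKM with the Sox12 vector, a log2 change of 8.34. A value per gene does not separate transcripts of the vector from those of the endogenous gene. Foxp3, the lineage transcription factor of Treg, had 88.2 FPKM in untreated Treg and 84.9 FPKM in DSS Treg. In the transduced cells Foxp3 had 20.9 FPKM with the mock vector and 127 FPKM with the Sox12 vector, a log2 change of 2.55 and a ratio of 6.08.

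**Figure D1:**
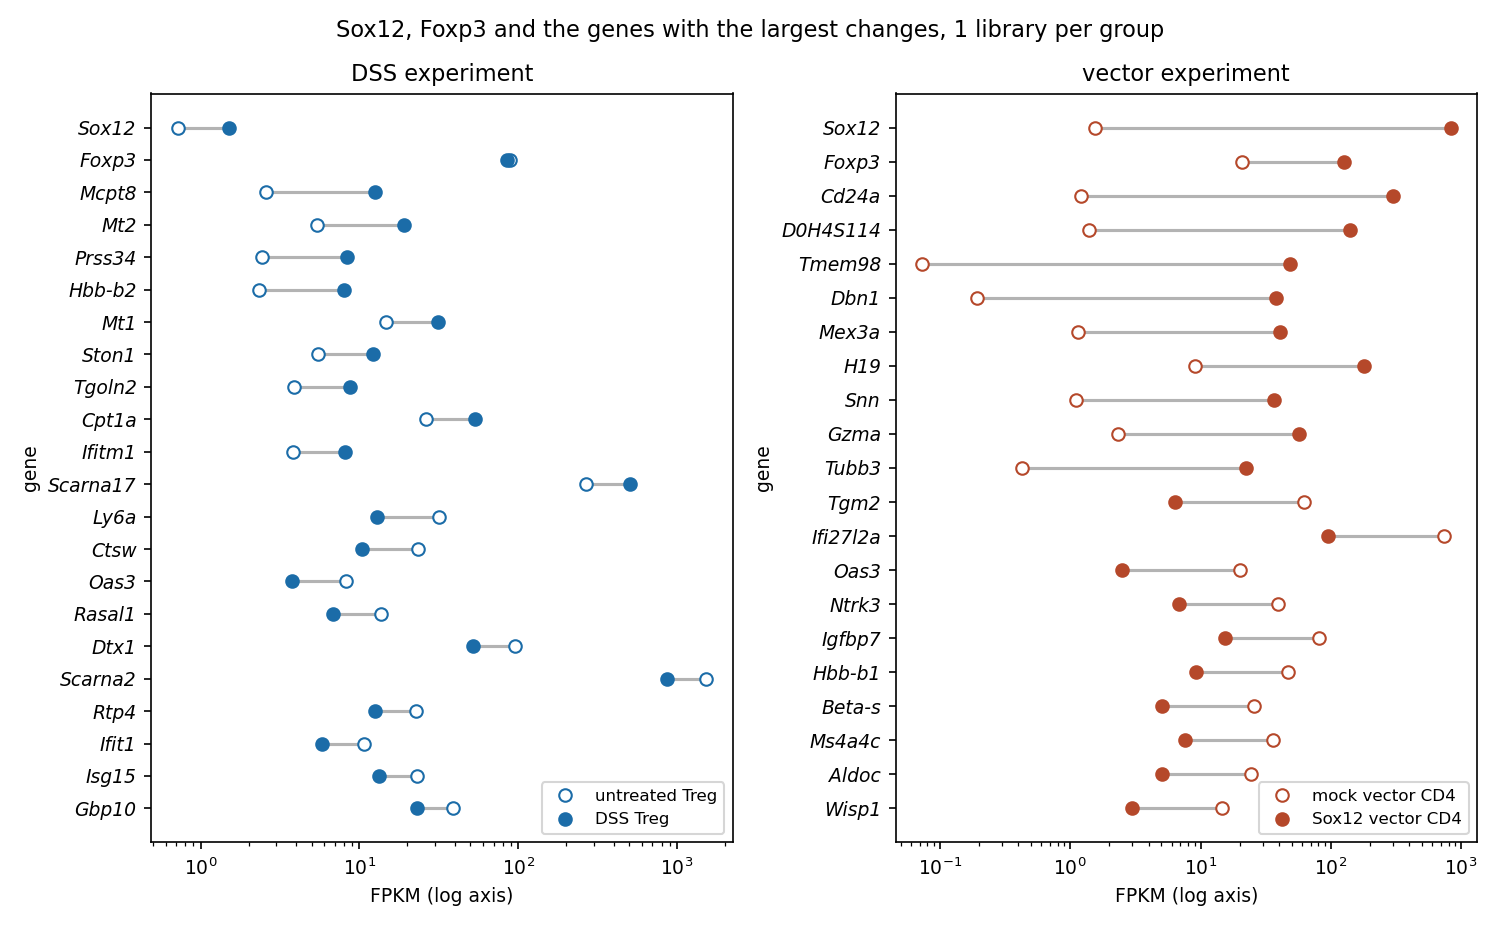
FPKM on a log axis for Sox12, Foxp3 and the 10 genes with the largest change in each direction, in the DSS experiment (left, blue) and the vector experiment (right, red). Open circles are the untreated Treg or mock vector library and filled circles the DSS Treg or Sox12 vector library, 1 library each, and Foxp3 lay at 88.2 and 84.9 FPKM in the DSS experiment and at 20.9 and 127 FPKM in the vector experiment.

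In the library of Treg from DSS-treated mice, genes of the interferon-response list and cholesterol genes were lower than in untreated Treg, and genes of proliferation, metallothioneins and markers of basophils and red cell precursors were higher. The interferon-response list had 23 of 23 members lower, with a median log2 change of -0.61. The differences were small for most genes. The middle of the distribution lay at 0.05, with 5% of genes below -0.20 and 5% above 0.31, and 20 genes were at least 2 times higher and 8 at least 2 times lower on the log2(FPKM + 1) scale.

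Among genes with a mean of at least 5 FPKM that the naming rule admits, the one most above untreated Treg was Mcpt8, a basophil granule protease. It had 2.56 FPKM in untreated and 12.6 FPKM in DSS Treg (ratio 4.92). Prss34, a protease of basophils and mast cells, had 2.44 and 8.35 FPKM. The metallothioneins Mt2 and Mt1, which bind zinc and copper, had 5.38 and 19.2 FPKM and 14.6 and 31.3 FPKM. Hbb-b2, an adult beta-globin, had 2.34 and 8.05 FPKM, and its reads may be shared with near-identical globin genes. Cpt1a, which admits long-chain fatty acids to mitochondria, had 26.4 and 53.3 FPKM (ratio 2.02). Ston1 had 5.47 and 12.1 FPKM, Tgoln2 3.89 and 8.73 FPKM, and the small Cajal body RNA Scarna17 267 and 504 FPKM. Ifitm1, an interferon-inducible gene outside the interferon-response list, had 3.80 and 8.08 FPKM and so differed in the direction opposite to that list.

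Of the same genes the one most below untreated Treg was Ly6a, the interferon-inducible surface antigen Sca-1, with 31.6 FPKM in untreated and 12.8 FPKM in DSS Treg (ratio 0.406). Ctsw, which encodes cathepsin W, had 23.5 and 10.4 FPKM. The interferon-induced genes Oas3 (8.28 and 3.77 FPKM), Rtp4 (22.7 and 12.6 FPKM), Ifit1 (10.7 and 5.77 FPKM), Isg15 (23.1 and 13.3 FPKM) and Gbp10 (39.0 and 23.0 FPKM) were also among the 10. Gbp10 has close copies whose reads it may share. Dtx1, a regulator of Notch signalling, had 96.0 and 51.5 FPKM, Rasal1, a Ras GTPase-activating protein, had 13.7 and 6.86 FPKM, and the small Cajal body RNA Scarna2 had 1527 and 864 FPKM.

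The gene lists fixed beforehand gave the following picture. The median of the interferon list lay below all 10000 random lists matched on mean expression. Its largest difference was that of Ifi44, with 3.08 FPKM in untreated and 0.802 FPKM in DSS Treg (log2 change -1.18). Cholesterol synthesis genes were lower in 17 of 17 cases, with a median of -0.27, again below all random lists. Proliferation genes were higher in 25 of 25 cases, with a median of 0.25 that lay above all random lists. No member reached 2 times. Markers of erythroid and myeloid precursors, which are dividing cells, were also higher in this library, and the values do not show which cells the proliferation transcripts came from. Pcna, the sliding clamp of DNA replication, had 132 and 145 FPKM, and Hmgb2 had 66.5 and 75.9 FPKM. Targets of IL-2 and STAT5 were lower in 9 of 13 cases (median -0.12, percentile 0.01), with Ccnd2 at 103 and 83.9 FPKM and Pim1 at 107 and 109 FPKM. Heat shock genes were lower in 9 of 10 cases (median -0.20, percentile 0.01), with Hsp90ab1 at 545 and 464 FPKM and Hspa8 at 683 and 623 FPKM.

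The Treg core list had 13 of 21 members lower and 8 higher (median -0.05, percentile 0.19), and no member differed by 2 times. Folr4, now named Izumo1r, had 283 and 263 FPKM, and the IL-2 receptor beta chain Il2rb had 237 and 211 FPKM. Small differences with outlying percentiles were also found in endoplasmic reticulum stress genes (median -0.07, percentile 0.54, Hspa5 at 183 and 165 FPKM, Hsp90b1 at 181 and 160 FPKM), TGF-beta pathway genes (9 of 14 lower, median -0.04, percentile 0.78, Tgfb1 at 75.2 and 78.7 FPKM, Tgfbr2 at 64.9 and 63.1 FPKM), and naive and lymphoid homing genes (10 of 13 lower, median -0.06, percentile 1.27, with Tcf7 among the 3 higher at 291 and 325 FPKM). Chemokine receptors and integrins were higher in 12 of 16 cases, with a median of 0.12 (percentile 99.4). The most abundant members, Itgb7 at 288 and 250 FPKM and Itgb2 at 188 and 168 FPKM, were among the 4 that were lower. Th2 genes had a median of 0.18 (percentile 97.8), with Gata3 at 38.8 and 40.7 FPKM and Stat6 at 68.4 and 69.2 FPKM. With a mean of at least 5 FPKM required, the percentiles of these last 2 lists were 89.0 and 79.1, and with a pseudocount of 5 they were 95.5 and 91.4.

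The medians of the remaining T cell lists lay inside the central 95% of random lists. With a pseudocount of 5 the effector Treg (percentile 97.6), Th17 (98.2) and glycolysis (99.2) lists lay above that range, and with a mean of at least 5 FPKM required the T cell receptor list (2.15) lay below it. Effector Treg genes had a median of 0.11 (percentile 96.4), with Batf at 42.1 and 45.1 FPKM and Maf at 39.6 and 44.1 FPKM. Th17 genes had a median of 0.18 (percentile 96.6), with Stat3 at 56.9 and 60.6 FPKM and Ccr6 at 11.4 and 13.7 FPKM. T cell identity genes had a median of -0.02 (percentile 18.96), with Cd3e at 468 and 473 FPKM and Cd3g at 428 and 443 FPKM. The same range held Tfh genes (percentile 33.4, Sh2d1a at 51.3 and 52.0 FPKM, Icos at 36.90 and 37.97 FPKM), coinhibitory receptors (90.6, Ctla4 at 128 and 146 FPKM, Tigit at 43.7 and 58.2 FPKM) and T cell receptor early response genes (4.21, Junb at 235 and 258 FPKM, Nfkbia at 173 and 168 FPKM). It also held p53 and apoptosis genes (80.6, Mcl1 at 225 and 219 FPKM, Trp53inp1 at 108 and 103 FPKM), glycolysis genes (94.9, Ldha at 204 and 218 FPKM, Pkm2 at 168 and 174 FPKM), oxidative phosphorylation genes (92.3, Cox4i1 at 306 and 322 FPKM, Atp5b at 295 and 309 FPKM) and ribosomal protein genes (13.3, Rplp1 at 3275 and 3208 FPKM, Rps15 at 1504 and 1442 FPKM). Th1 genes (24.9), whose small positive median like that of the Tfh genes turned negative when the median change was set to 0 or the 75th percentiles were made equal, contained Ccl3, a chemokine of activated T cells and myeloid cells, at 0.288 and 2.83 FPKM.

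Markers of other cell types were measured alongside these groups. Erythroid genes were higher in DSS Treg in 10 of 10 cases, with a median of 0.57 above all random lists. The most abundant, Hba-a1, had 250 and 388 FPKM. Of the neutrophil and granule list the 3 genes past the filter were higher (median 0.56, percentile 99.9). They included the myeloid precursor granule genes Mpo at 9.99 and 15.2 FPKM and Prtn3 at 4.24 and 8.16 FPKM. The mature neutrophil genes of that list, S100a8 (1.08 and 0.678 FPKM) and S100a9 (1.19 and 0.449 FPKM), were below the filter and lower. Without the filter the median was 0.29 with 3 higher and 2 lower. Plasma cell markers were lower in 5 of 5 cases (median -0.17, percentile 0.49, Igj, now named Jchain, at 277 and 231 FPKM, Xbp1 at 56.4 and 52.8 FPKM). NK and CD8 T cell markers were lower in 4 of 4 (median -0.14, percentile 0.92, Nkg7 at 18.8 and 16.0 FPKM, Cd8b1 at 5.95 and 5.40 FPKM). B cell markers (median -0.06, percentile 7.58, Cd74 at 30.2 and 22.6 FPKM, Cd79b at 5.48 and 5.23 FPKM) and macrophage markers (median 0.13, percentile 79.2, Lyz2 at 8.30 and 6.36 FPKM, Cybb at 6.21 and 6.90 FPKM) lay inside the range of random lists. Single listed genes past the filter were Itga2b for platelets (0.878 and 1.40 FPKM), Pecam1 for endothelium (48.5 and 46.7 FPKM), Cela1 for pancreas (1.61 and 2.16 FPKM) and the X-linked Xist (50.4 and 49.4 FPKM). Of the SoxC and other Sox genes, Sox4 had 4.18 and 3.92 FPKM, and Sox6, below the filter, had 0.674 and 1.30 FPKM.

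The counts of this comparison depended on the pseudocount. With a pseudocount of 0.1 there were 39 higher and 20 lower genes, and with a pseudocount of 5 there were 6 and 3.

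In transduced CD4 T cells the difference between the libraries was wider. With the Sox12 vector, Foxp3, cytotoxic genes, most Th1 genes and several genes best known from neurons were higher, and glycolysis genes and Il2 were lower. There were 525 genes at least 2 times higher and 207 at least 2 times lower on the log2(FPKM + 1) scale, which also holds for the list members below. Of these genes, 25 and 28 were small RNAs and 19 and 20 predicted or unnamed loci. Of all genes past the filter, 5% lay below -0.68 and 5% above 0.98.

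Among genes with a mean of at least 5 FPKM that the naming rule admits, the one most above the mock vector after Sox12 itself was Cd24a, a surface glycoprotein anchored by lipid, with 1.20 FPKM with the mock vector and 301 FPKM with the Sox12 vector (log2 change 7.10). D0H4S114, now named Nrep, had 1.39 and 141 FPKM, and Tmem98 had 0.0728 and 48.7 FPKM. The actin-binding protein drebrin (Dbn1) had 0.192 and 37.9 FPKM and the neuronal tubulin Tubb3 had 0.425 and 22.4 FPKM. Mex3a, which encodes an RNA-binding protein, had 1.15 and 41.0 FPKM, Snn had 1.12 and 36.4 FPKM, and the imprinted long non-coding RNA H19 had 9.10 and 180 FPKM. Gzma, a granzyme of cytotoxic lymphocytes, had 2.35 and 57.2 FPKM (log2 change 4.12).

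By the same rule the genes most below the mock vector were Tgm2, which encodes a transglutaminase, with 62.2 FPKM with the mock vector and 6.38 FPKM with the Sox12 vector (log2 change -3.10), and the interferon-induced genes Ifi27l2a (736 and 94.7 FPKM) and Oas3 (20.2 and 2.52 FPKM). The neurotrophin receptor gene Ntrk3 had 39.0 and 6.82 FPKM, Igfbp7 had 81.2 and 15.4 FPKM, Ms4a4c had 36.2 and 7.66 FPKM, the aldolase gene Aldoc had 24.6 and 5.10 FPKM, and Wisp1, now named Ccn4, had 14.7 and 2.96 FPKM. The beta-globin entries Hbb-b1 (46.6 and 9.27 FPKM) and Beta-s (25.5 and 5.05 FPKM) were in the same group, and their near-identical sequences make the split between them uncertain.

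The Treg core list split evenly, with 10 of 20 members higher and 10 lower. Its median of -0.05 (percentile 46.8) was positive without the filter and with equal totals without the 20 highest genes. Foxp3 was the 1 member at least 2 times higher on the log2(FPKM + 1) scale. By the ratio of the FPKM themselves, Il10 (0.786 and 2.23 FPKM, ratio 2.84), Nt5e (2.39 and 5.22 FPKM, ratio 2.18) and Fgl2 (3.24 and 6.86 FPKM, ratio 2.12) also passed 2. Il2rb was higher at 243 and 352 FPKM. Apart from Foxp3, these genes were chosen after their values were seen. The 4 members at least 2 times lower included the semaphorin receptor Nrp1 (23.6 and 5.94 FPKM), Folr4 (124 and 38.9 FPKM) and the IL-35 subunit Ebi3 (54.9 and 17.7 FPKM). Of the effector Treg list, Gzmb, a granzyme, had 708 and 2735 FPKM, while the growth factor Areg (10.4 and 2.32 FPKM), Pparg (6.25 and 1.74 FPKM) and the chemokine receptor Ccr4 (94.1 and 38.8 FPKM) were lower. The median of that list was 0.33 (percentile 99.9), but -0.42 with a mean of at least 5 FPKM required. Naive and lymphoid homing genes had a median of 0.42 (percentile 99.99) and 4 members at least 2 times higher, namely Klf2 (8.06 and 46.7 FPKM), Igfbp4 (74.3 and 347 FPKM), Id3 (12.3 and 41.9 FPKM) and S1pr1 (15.3 and 40.5 FPKM).

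The NK and CD8 T cell list, which is a list of markers of other cell types, had 10 of 10 members higher, 8 of them at least 2 times, with a median of 1.46 above all random lists. Perforin (Prf1) had 30.3 and 135 FPKM, Cd8a 0.580 and 5.58 FPKM and the NKG2D gene Klrk1 6.35 and 21.4 FPKM. Th1 genes were higher in 10 of 12 cases, 4 of them at least 2 times, with a median of 0.59 above all random lists. The transcription factor Stat4, chosen after its values were seen, was lower at 57.9 and 34.9 FPKM. The 4 genes at least 2 times higher were interferon-gamma (Ifng) at 41.3 and 191 FPKM, its transcription factor Tbx21 at 5.07 and 16.2 FPKM, and the chemokines Ccl3 at 166 and 449 FPKM and Ccl5 at 12.0 and 28.3 FPKM. Beside them, 3 macrophage markers passed the filter (median 1.61, percentile 99.8), with the signalling adaptors Fcer1g at 18.8 and 67.1 FPKM and Tyrobp at 2.33 and 9.18 FPKM, which NK cells also express. Without the filter the percentile of the macrophage list was 81.4.

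Interferon-response genes went both ways, with 4 members at least 2 times higher and 5 at least 2 times lower (median -0.02, percentile 41.5). The type I response genes Irf7 (17.6 and 3.73 FPKM), Isg15 (18.6 and 4.77 FPKM) and Oas1a (2.73 and 0.245 FPKM) were lower with the Sox12 vector, and the GTPase gene Iigp1 (4.36 and 14.1 FPKM) was higher. The sign of this median depended on the filter, with -0.21 (percentile 0.15) without one and 0.43 (percentile 99.95) at a mean of at least 5 FPKM, and it was 0.035 with equal totals without the 20 highest genes.

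Among signalling lists, IL-2 and STAT5 targets were higher in 8 of 13 cases with a median of 0.25 (percentile 99.9), and the cytokine signalling inhibitor Socs3 had 7.72 and 23.9 FPKM. The 5 lower members were Ccnd3 (111 and 68.3 FPKM), Lta (604 and 430 FPKM), Il2ra (629 and 568 FPKM), Socs1 (52.7 and 48.2 FPKM) and Cish (180 and 173 FPKM). TGF-beta pathway genes had a median of 0.33 (percentile 99.5) and 3 members at least 2 times higher, the signal transducer Smad3 (4.50 and 15.7 FPKM), the corepressor Tgif1 (17.9 and 47.6 FPKM) and the receptor Tgfbr1 (6.55 and 15.3 FPKM). The p53 and apoptosis list had 11 of 14 members higher and a median of 0.33 (percentile 99.95). At least 2 times higher were Trp53inp1 at 12.9 and 45.2 FPKM, the proapoptotic BIM gene Bcl2l11 at 10.2 and 31.7 FPKM and Pmaip1 at 7.90 and 18.3 FPKM. The 3 lower members were Cdkn1a (138 and 119 FPKM), Mdm2 (42.2 and 41.2 FPKM) and Sesn2 (10.8 and 8.97 FPKM). T cell receptor early response genes had a median of -0.22 (percentile 0.55), with Il2 at 35.1 and 8.40 FPKM and the transcription factor Irf4 at 96.7 and 45.3 FPKM. Tfh genes (median -0.47, percentile 0.20) included Cd200 at 85.8 and 34.3 FPKM, and Th17 genes (median -0.38, percentile 1.02) included Ccr6 at 14.8 and 5.48 FPKM. Without the filter the percentiles of these last 2 lists were 10.6 and 27.8.

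Glycolysis genes were lower in 15 of 16 cases, with a median of -0.71 below all random lists. Bnip3, a mitochondrial protein induced by hypoxia, had 49.3 and 21.0 FPKM and the lactate exporter gene Slc16a3 had 81.7 and 38.9 FPKM. Cholesterol synthesis genes were lower in 17 of 17 cases (median -0.31, percentile 0.01, Hmgcs1 at 148 and 131 FPKM, Fdps at 130 and 98.8 FPKM), and in 14 of 17 once the totals without the 20 highest genes were made equal. Ribosomal protein genes were lower in 21 of 22 cases (median -0.34, percentile 0.36), with Rplp1 at 3230 and 2242 FPKM and Rps15 at 1816 and 1320 FPKM. Oxidative phosphorylation genes lay at percentile 48.9, with Atp5b at 666 and 607 FPKM and Cox4i1 at 408 and 379 FPKM.

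Proliferation genes lay at percentile 64.3. Their median and that of the oxidative phosphorylation genes, both just below 0, were just above 0 with equal totals without the 20 highest genes. Of the proliferation list, Stmn1, a regulator of microtubules, had 335 and 945 FPKM. T cell identity genes had a median of -0.25 (percentile 6.90), with Cd5 at 189 and 81.7 FPKM. Chemokine receptors and integrins lay at percentile 89.4, with Ccr2 at 4.58 and 10.4 FPKM. Th2 genes lay at percentile 28.6, with Il5 at 17.9 and 7.62 FPKM. With a mean of at least 5 FPKM required, the medians of these last 2 lists were -0.22 and -0.57, at percentiles 1.75 and 0. Coinhibitory receptors lay at 29.5, with Havcr2 at 6.63 and 21.2 FPKM and Cd160 at 2.12 and 6.46 FPKM. Heat shock genes lay at 38.8, with Hspa1b at 3.80 and 1.36 FPKM and its near-identical copy Hspa1a at 3.82 and 1.39 FPKM. Endoplasmic reticulum stress genes lay at 41.3, with Hsp90b1 at 379 and 382 FPKM and Hspa5 at 284 and 274 FPKM.

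Of markers of further cell types, B cell genes had a median of -0.44 (percentile 1.73), with H2-Ab1 at 21.6 and 6.79 FPKM, and the percentile was 80.9 without the filter and 3.52 with a pseudocount of 0.1. Erythroid genes lay at percentile 14.3 over 3 genes. Fewer than 3 members passed the filter in the other lists, where Xbp1 had 145 and 81.2 FPKM and Sdc1 0.866 and 1.75 FPKM for plasma cells, Batf3 22.5 and 28.9 FPKM and Zbtb46 3.10 and 3.25 FPKM for dendritic cells, Pecam1 12.2 and 44.0 FPKM for endothelium, Cela1 1.03 and 1.63 FPKM for pancreas, Xist 60.8 and 64.2 FPKM for the sex-linked list, and Sox4 1.76 and 1.25 FPKM for the other Sox genes. With a pseudocount of 5 the size rule was met by 222 higher and 94 lower genes.

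**Figure D2:**
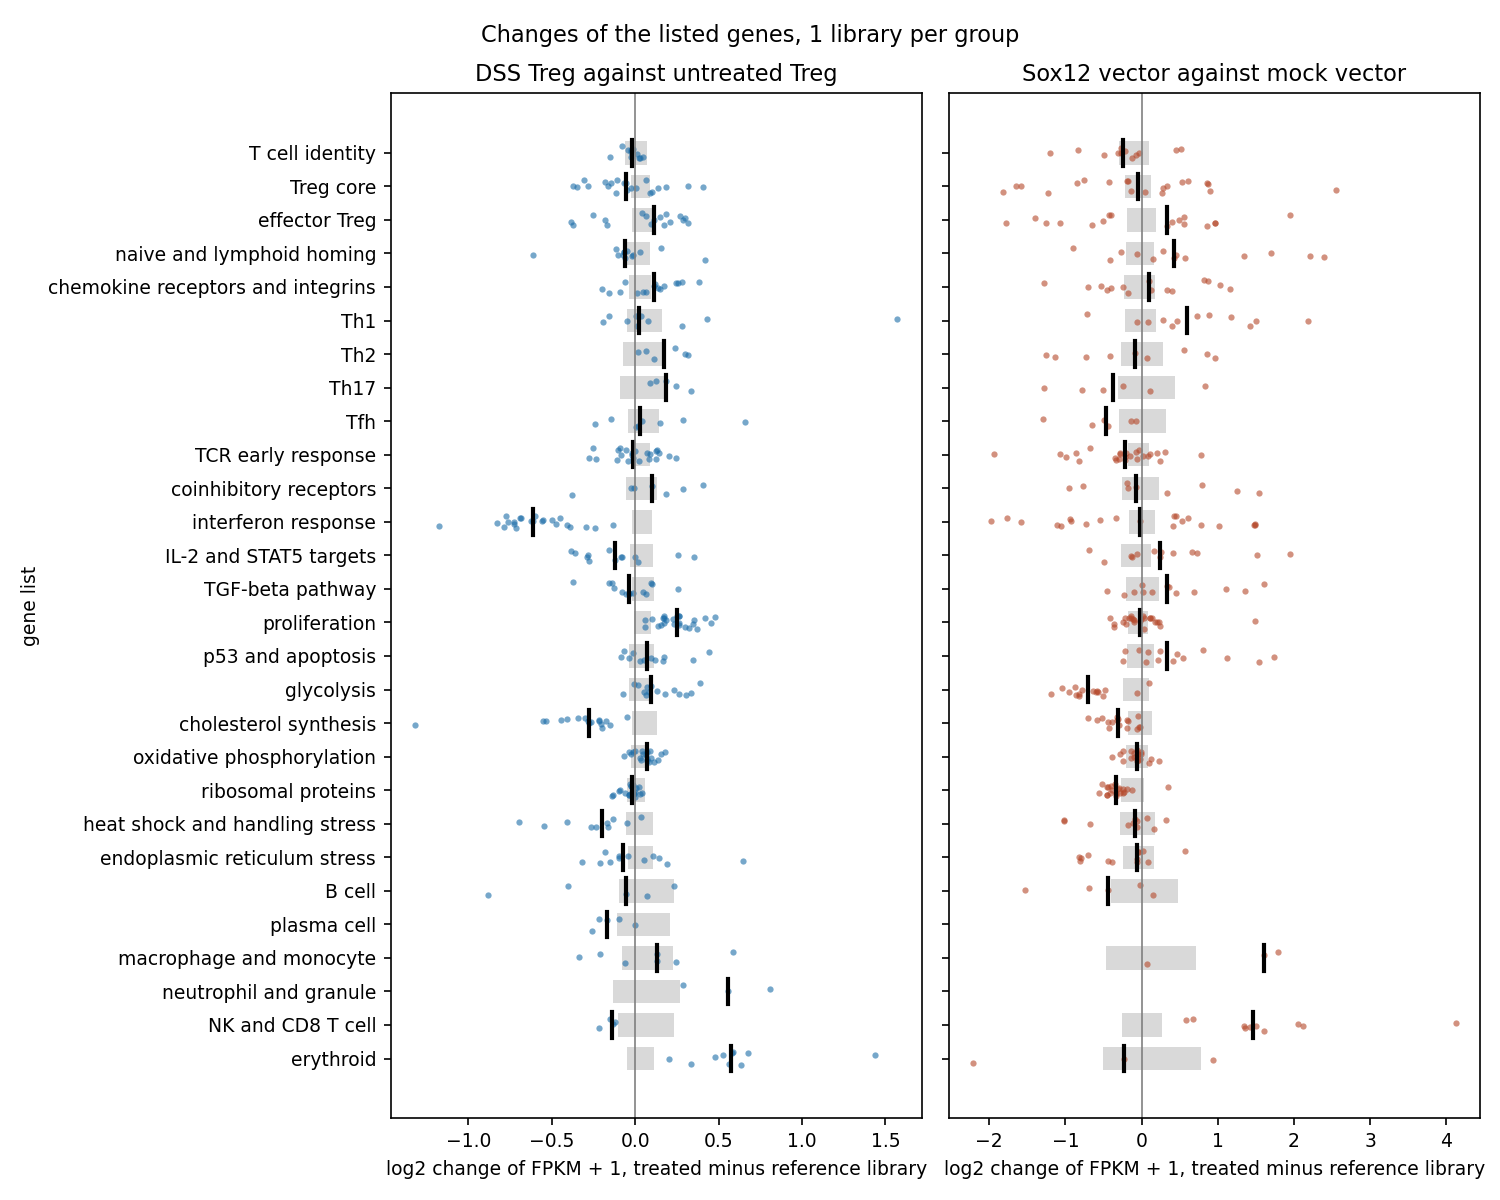
Log2 change of FPKM + 1 for each list member with a mean of at least 1 FPKM (points), the list median (black line) and the central 95% of the medians of 10000 random lists matched on mean expression (grey bar), for the DSS experiment (left) and the vector experiment (right). The horizontal scales differ, lists with fewer than 3 members are left out, and the interferon list lay at -0.61 in the DSS experiment and the NK and CD8 T cell list at 1.46 in the vector experiment.

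The changes of the 2 experiments were compared over the 9958 genes past the filter in both. Across these genes, which are not independent replicates, Pearson's r was 0.065 and Spearman's rho 0.035. At least 2 times higher in both were 3 genes, Mt2, Ccl3 and Gsta4, where 0.305 would be shared by independent lists of 9 and 337 genes. At least 2 times lower in both were 2 genes, Gm12238 and Lst1, against 0.0623 for lists of 5 and 124. These values for independent lists take every gene as equally likely to pass the size rule, whatever its level. Ccl3 was listed in the DSS experiment only through its DSS value (0.288 and 2.83 FPKM). Gsta4, a glutathione transferase, had 1.66 and 4.65 FPKM in the DSS experiment and 0.402 and 4.46 FPKM in the vector experiment. Lst1 had 4.46 and 1.35 FPKM in the DSS experiment and 15.01 and 5.94 FPKM in the vector experiment, where Mt2 had 8.55 and 25.04 FPKM. The predicted gene Gm12238 is listed at 0 in both the DSS and the Sox12 vector library. Lower in DSS Treg and higher with the Sox12 vector was 1 gene, Ctsw, with 9.14 and 36.7 FPKM in the vector experiment, and 0 genes went the other way. With so few shared genes, a pseudocount of 0.1 gave 7 higher and 7 lower in both, and a pseudocount of 5 gave 1 and 0.

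**Figure D3:**
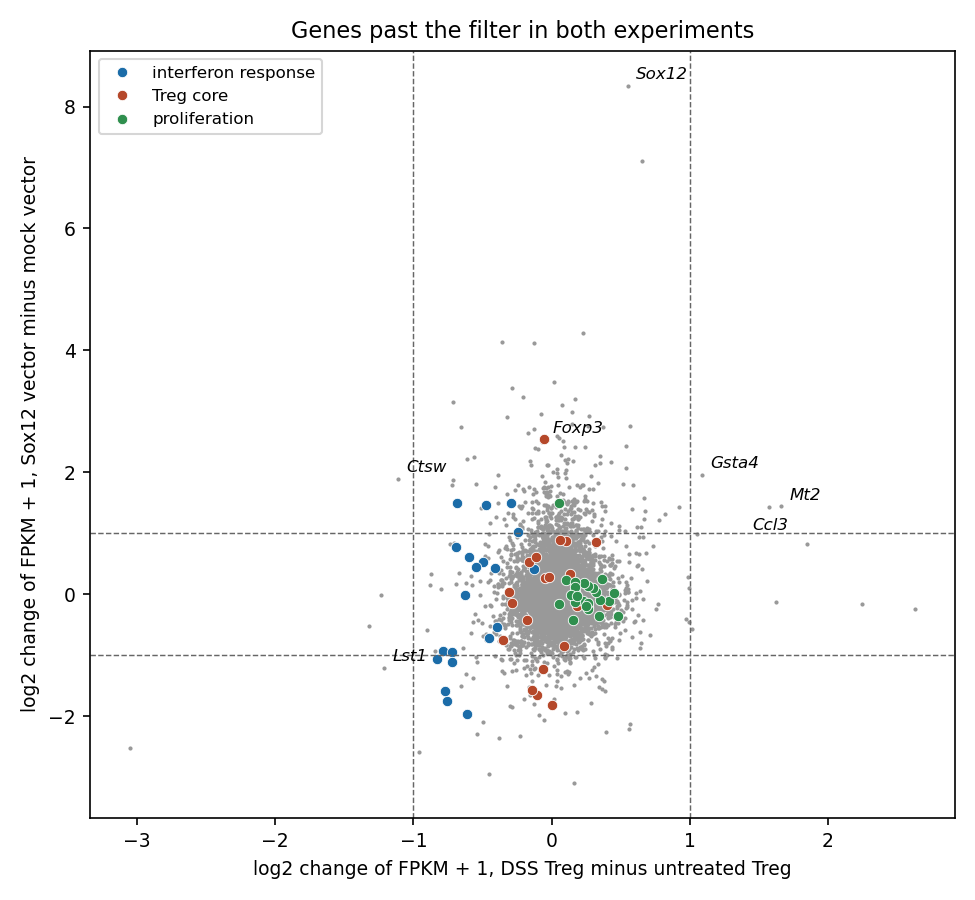
Log2 change of FPKM + 1 in the DSS experiment (horizontal, DSS Treg minus untreated Treg) against that in the vector experiment (vertical, Sox12 vector minus mock vector) for 9958 genes, 1 point per gene, with 3 lists in colour and dashed lines at the size rule of 1 in either direction. Interferon-response genes all lie left of 0 on the horizontal axis and on both sides of 0 on the vertical axis, and Sox12 lies at 0.55 and 8.34.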

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

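Counts without small RNAs and unnamed loci were chosen after the data had been seen, and all other alternatives before. With a pseudocount of 0.1, 39 genes were higher and 20 lower in DSS Treg, and 335 were lower with the Sox12 vector. With a pseudocount of 5 these counts were 6, 3 and 94, and 222 were higher with the Sox12 vector. With a mean of at least 5 FPKM required, 8 genes were higher and 2 lower in DSS Treg and 322 were higher with the Sox12 vector. A size rule of 1.5 left 9 higher and 2 lower in DSS Treg and 242 higher and 73 lower with the Sox12 vector, which follows from its construction. Genes higher in both experiments numbered 7, 1, 1 and 0, and genes lower in both 7, 0, 0 and 1, under pseudocounts of 0.1 and 5, the stricter filter and the stricter size rule. Without small RNAs and unnamed loci 1 gene was lower in both. The change of Sox12 with its vector was 8.97 and 6.99 with pseudocounts of 0.1 and 5. A pseudocount enters every low value, and the cause of the other differences was not tested.

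The 3 scalings moved the median of all genes by less than 0.1, and the share of higher genes among those past the size rule by less than 10 points. Of 6 counts, 23 of 60 alternative values differed by more than 1.5 times. Of 1272 alternative changes of named genes 35 moved by more than 1.5 times, and 0 changed sign among genes past the size rule. Of 478 alternative list medians 4 were counted as moved, and 2 changed sign among lists outside the range of random lists. More medians than these 4 differed by over 1.5 times. Without the filter the macrophage, Tfh and Th17 medians of the vector experiment were 0.045, -0.11 and -0.060, against 1.61, -0.47 and -0.38. In the DSS experiment the neutrophil and granule median went from 0.56 to 0.29, and that of plasma cell markers from -0.17 to -0.088. The 2 that changed sign were the effector Treg list of the vector experiment (-0.42 with a mean of at least 5 FPKM required) and its B cell list (0.054 without the filter). Each of these settings changes which members are counted. Genes below 1 FPKM in both DSS libraries are outside the table, and at 1 FPKM a difference of about 10% lies within the counting error of the vector libraries.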

Other observations

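The tests of dilution, of library scaling, of the pooled B cell, plasma cell, macrophage and NK or CD8 T cell markers, and of Cd8b1 were chosen after the values they use had been seen. The gene lists of the other tests were written after each pattern was seen and before their genes were looked up. The exception is 7 genes whose values had already been seen, which were left out after values for the full lists had been computed. In these full lists the interferon medians had the same directions, and the imprinted genes gave another answer, given below.

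Interferon genes were lower in the DSS Treg library. Dilution of Treg RNA by other cells would lower T cell identity genes by about as much, and their median change was -0.021. Library scaling moved the median of the list to -0.63 at the nearest to 0. Further targets of type I interferon and interferon-gamma, not in the first list, were lower in 30 of 30 cases with a median of -0.33, so a weaker interferon response may be a candidate explanation, although the inducible gene Ifitm1 was higher. No test here separates the treatment from any other difference between the animals of 2 single libraries.

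Erythroid and basophil transcripts were higher in the DSS Treg library. A larger number of cells of every other type is argued against, although not for each type alone. Pooled, 21 markers of B cells, plasma cells, macrophages and NK or CD8 T cells had a median of -0.12, with 6 higher. The macrophage markers among them were mixed, with 4 higher, 3 lower and a median of 0.13. The neutrophil and granule list, which was not part of this test, was higher. A further erythroid list was higher in 19 of 19 cases with a median of 0.47, among them Aqp1 at 29.3 and 46.9 FPKM and Gata1 at 17.1 and 22.2 FPKM, so RNA of erythroid cells may have entered both sorts, and more of it the DSS sort. A basophil and mast cell list had 4 of 14 members past the filter and a median of 0.41. Of these, Gata2 and Cd200r3 were listed only through their values in the DSS library, which raises this median. The other members past the filter were split, with Il3ra at 4.80 and 4.58 FPKM and Kit at 2.65 and 3.72 FPKM. This list therefore cannot decide whether the same holds for basophils. A sort on human CD2 under Foxp3 would remove both cell types, and whether their number in the spleen differed is not known from these data.

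Cytotoxic genes were higher in the Sox12 vector library. NK cells in the culture would raise further NK receptors. Of a list of 18 such genes 12 passed the filter, and 11 of 12 were higher with a median of 0.94, short of the value of 1 set for them beforehand. Klra3 (0.551 and 1.86 FPKM), Klra6, Klrb1a and Klrc3 passed the filter only through their values in the Sox12 vector library, which raises this median. Of the genes below the filter, S1pr5 was listed at 0 in both libraries. The most abundant of the 12, Klrc1, had 28.36 and 35.04 FPKM. Activated T cells also express such receptors, which keeps it open, and the effect of the vector and NK cells cannot be told apart here. For CD8 T cells the change of Cd8b1 was 0.58, between the bounds set, so these cannot be told apart either, although a selection of naive CD4 T cells would remove both.

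The interferon list split in the Sox12 vector library. Further interferon-gamma targets had a median of 0.21 (percentile 99.0) and further type I targets one of -0.50 (below all random lists), a difference of 0.71. The interferon-gamma targets were themselves mixed, with 7 of 12 higher. With Ifng also higher, a shift from type I interferon to interferon-gamma signalling may be a candidate explanation.

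Several neuronal genes were among those most above the mock vector. Of a list of 25 other neuronal differentiation genes 10 passed the filter, 8 of them higher, with a median of 1.33 at percentile 100. Tubb2b had 11.0 and 82.0 FPKM, Marcksl1 31.5 and 210.2 FPKM and Marcks 5.40 and 34.7 FPKM, while Gap43 had 34.2 and 10.5 FPKM. Other members of the list, such as Dcx and Elavl4, were listed at 0 in both libraries, so the result covers part of the list. The cause was not tested.

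The imprinted genes H19, Igf2 (0.0395 and 13.0 FPKM) and Cdkn1c (0.318 and 10.2 FPKM) were higher with the Sox12 vector, the last 2 chosen after their values were seen. A wider imprinted list had a median of 0.30 at percentile 96.9 over 9 genes, short of the bound set beforehand. With the 2 genes whose values had been seen put back, the median was -0.04 at percentile 44.0. A result that turns on 2 genes gives no support to a change of imprinted genes as a group, although Plagl1 (1.26 and 11.7 FPKM), Dlk1 (0.435 and 6.17 FPKM) and Rian (0.199 and 6.19 FPKM) were higher.

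Some genes fall outside the rule for naming and were chosen after their values were seen. In the DSS experiment the chemokine gene Ccl6 had 0.0823 and 7.46 FPKM, Cpa3 1.79 and 5.16 FPKM, Ctsg 1.82 and 5.72 FPKM, Mcpt4 1.46 and 4.26 FPKM and Hdc 0.451 and 2.11 FPKM. Ndufs5, a subunit of respiratory complex I, had 9.20 and 0.00048 FPKM. In the vector table, a row named 5-Sep, whose gene name had been turned into a date, had 1.26 and 12.7 FPKM.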
